A study of Xenopus tropicalis with 18 samples.

How the data were processed

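RNA was measured in 18 libraries from Xenopus tropicalis embryos at stage 33, in 6 groups of 3, each library a pool of 8 explants. Per the labels' protocols, drugs were given from stage 15 to stage 33, at 40 µM for cyclopamine and 100 nM for BMS493, and morpholinos were injected at the 2-cell stage, 1 ng in all and 500 pg in each cell. The labels give the head with pharynx and hindgut controls 0.1% DMSO, the foregut control 0.1% DMSO with a mismatch morpholino, and the Rfx6 group 0.1% DMSO with the Rfx6 morpholino. For the drug groups they name only the drug. Whether drug-treated embryos were also injected with a mismatch morpholino is not stated. If they were not, drug and morpholino differ together in the comparisons of each drug with control foregut. The label field named batch holds these treatments and no sequencing batch. Which parents or clutch an explant pool came from is not given in the sources used here, so p-values measure the spread between libraries. This is the spread between pools only if no libraries shared explants or RNA, which is open for replicates 1 and 2 of the treated groups.

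Libraries were made with a stranded kit that selects messenger RNA, per the labels' protocols. The authors deposited estimated counts per gene as whole numbers (100% of values), and RSEM 1.3.0 and Bowtie2 are named in the submitters' processing notes. The genome build and annotation are not given in the sources used here. The authors also deposited TPM values, scaled by them for length and depth, in a second table with the same 18 libraries. Each count column was matched best by the TPM column of its own library, in 18 of 18. One entry without a gene name held 0 counts. Columns were assigned by names that match the sample titles. The description lines of BMS493 replicates 2 and 3 carry the name of replicate 1, and the titles were followed. How RSEM shared reads between near-identical gene copies was not examined, so single identifiers from such families are uncertain.

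The tables hold 28863 identifiers. A reference table of 28858 RefSeq genes matched 0 of them, so 35 gene lists and a set of named genes fixed by symbol before the data were examined could not be used. That rule named the perturbed and directly responding genes, the largest increases and decreases with a symbol and the leading members of each list. Without symbols, 2 identifiers that rose and 2 that fell were chosen after their values were seen, as the largest changes of each drug comparison. Genome positions are not given for the same reason.

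Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust fitting, TMM scaling and edgeR's expression filter with a minimum count of 10. The 9 control libraries were fitted together (18551 genes tested) and the 12 foregut libraries together (18542 genes tested), with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and genes that also changed at least 2-fold were counted separately. The common biological coefficient of variation was 0.119 in the control fit and 0.139 in the foregut fit. Totals of 26006163 to 96814679 counts per library set the counting precision, and a gene without counts in a group allows up to 3 counts over that group, which covers counting error only.

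Region-enriched genes were at least 2-fold higher and past the threshold against both other control regions, and the anterior and posterior lists came from hindgut against head with pharynx at the same limits. These rules were fixed before the data were examined. The classes shared by 2 regions (at least 2-fold above the remaining region in each), the axis position and the groups of genes that set a treatment apart were defined afterwards. By these definitions the anterior list holds the genes enriched in head with pharynx and those shared by head with pharynx and foregut. The posterior list holds the hindgut-enriched genes and those shared by foregut and hindgut. Results of these lists are therefore not separate. Lists were tested with camera and fry in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. The axis position is the place of a library's mean log2 CPM over the anterior and posterior lists between the hindgut and head with pharynx means, with a prior count of 2. Overlaps were set beside the number that independent lists would share and beside 20 simulations of unchanged groups against the same controls.

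The edgeR step was tested on simulated counts with 50 genes changed at each fold, drawn from genes expected at 50 counts or more on average. Recovery of genes with fewer counts was not tested. Libraries were simulated as independent at the fitted spread, without the close and distant replicates of the real groups. The false calls therefore do not give the error rate in the real data. For BMS493 against control it recovered 28 of 50 genes changed 1.5-fold, 44 changed 2-fold, 47 changed 4-fold and 50 changed 8-fold, with 10 false calls among 17940 genes. For the Rfx6 morpholino against control the numbers were 25, 39, 49 and 50, with 9 false calls among 17968 genes. DESeq2 1.42.0 and limma were tested only for BMS493 against control, on 18542 genes. DESeq2 recovered 37, 47, 49 and 50 with 33 false calls, and limma 29, 46, 49 and 50 with 14 false calls.

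Replicate numbers in the titles were checked as pairs through the correlation of deviations from the group means. They passed the rule of every pair above 0.1 for foregut against hindgut (0.129, 0.296 and 0.125) and for Rfx6 morpholino against BMS493 (0.291, 0.263 and 0.438), and in no other comparison. The pairing comes from the titles' numbers and this check alone. Between Rfx6 morpholino and BMS493, replicates 1 and 2 correlated about as well across unlike numbers (0.276 and 0.257). The check therefore does not tell these replicates apart and cannot show that their numbers pair them. Between foregut replicate 3 and hindgut replicate 1 the correlation was 0.104. Replicates 1 and 2 of each treated group lay closer than other pairs, with a biological coefficient of variation of 0.0249 to 0.0564 against 0.0673 to 0.217, but differed by more than sampling noise (median chi-square ratio of at least 2.48), so they were kept as separate libraries and summed as an alternative.

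Alternatives fixed before the data were examined were another size factor (RLE), total counts alone, no filter and a stricter filter (1 CPM in 3 libraries), DESeq2, limma on log2(TPM + 1), all 18 libraries or only the 6 compared in a fit, the replicate number as a block, each library left out in turn, calls at 2-fold, and lists at 4-fold. Alternatives added after the data were seen were the summed replicates, 1 replicate number left out of all 3 treated groups, replicate 3 of BMS493 and Rfx6 morpholino both left out, and lists chosen with 1 control foregut library and tested against the others. List results were compared across settings as percent of the list, a form chosen after counts of members had been seen to shrink with shorter lists. Figures were drawn with matplotlib 3.10.9.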

Results

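Expression was measured by RNA sequencing in tissue dissected from Xenopus tropicalis embryos at Nieuwkoop and Faber stage 33, a tailbud stage at which the gut tube is being divided into organ territories. Each library was made from a pool of 8 explants of mesoderm and endoderm. Control explants came from 3 positions along the anterior-posterior axis, namely head with pharynx, foregut and hindgut. Foregut explants also came from embryos treated with cyclopamine, an inhibitor of the Hedgehog receptor component Smoothened, from embryos treated with BMS493, an inverse agonist of retinoic acid receptors, and from embryos injected with a morpholino against Rfx6, a transcription factor needed for endocrine pancreas development. There were 6 groups of 3 libraries, 18 in all, and the total count per library lay between 26006163 and 96814679. A level of 1 CPM, the count scaled to library size, therefore stood for at least 26 counts in every library. The files name genes only by identifiers, without symbols or positions, so the gene groups described here were defined by where in the control embryo their members were expressed.

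The comparison of control tissues asked how expression differed along the axis. Hindgut and head with pharynx, the ends of the axis, differed most, with 6236 genes higher and 5772 lower in hindgut among 18551 tested, of which 2752 and 2456 differed at least 2-fold. Foregut differed from head with pharynx in 5115 genes that were higher and 4901 that were lower (2421 and 1801 at least 2-fold). Foregut lay closer to hindgut, with 3087 genes higher and 3002 lower (1094 and 702 at least 2-fold). Among called genes the median absolute log2 fold change was 0.84 between the axis ends, 0.79 between foregut and head with pharynx and 0.64 between foregut and hindgut, with a median SE of 0.12 in each (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). The balance of directions rests on composition scaling, since total counts alone gave 3966 higher and 8919 lower in hindgut against head with pharynx, 3742 higher and 7495 lower in foregut against head with pharynx, and 5320 higher and 2098 lower in foregut against hindgut, with the median of all genes at -0.29, -0.18 and 0.15. Foregut control embryos had also received a mismatch morpholino, which the labels of the other control tissues do not mention.

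Genes at least 2-fold higher in a region than in both others numbered 1596 for head with pharynx, 523 for hindgut and 444 for foregut. Genes shared by foregut and hindgut and at least 2-fold lower in head with pharynx numbered 1422. Another 276 genes were shared by head with pharynx and foregut, and 59 were shared by head with pharynx and hindgut and were thus lowest in foregut. The remaining 14231 tested genes fell in none of these classes. Foregut and hindgut shared genes held 13 ± 0.452% of all counts in control foregut, 13.9 ± 0.616% in hindgut and 2.48 ± 0.123% in head with pharynx (SD, n = 3). Foregut-enriched genes held 1.36 ± 0.337% of counts in control foregut, 0.357 ± 0.0773% in hindgut and 0.122 ± 0.00307% in head with pharynx (SD, n = 3). Of the control foregut libraries, replicate 2 stood apart, with a mean of 2.31 log2 CPM over foregut-enriched genes where replicates 1 and 3 had 3.00 and 3.01.

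An anterior list of 2456 genes and a posterior list of 2752 genes were taken from the comparison of hindgut with head with pharynx, in which foregut libraries were not compared, although they entered the scaling, filter and spread of the fit. An axis position was computed from both lists, with 0 at the hindgut mean and 1 at the head with pharynx mean. Control foregut lay at 0.204 ± 0.012, near the hindgut end. Cyclopamine foregut lay at 0.325 ± 0.0191, BMS493 foregut at 0.652 ± 0.0871 and Rfx6 morpholino foregut at 0.318 ± 0.0895 (SD, n = 3 in each group). Every library of each treated group lay above every control foregut library, at an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Replicate 3 stood apart from replicates 1 and 2 in the BMS493 group, at 0.752 against 0.6 and 0.603, and in the Rfx6 morpholino group, at 0.422 against 0.263 and 0.27. The axis position was defined after the data were examined. It averages log2 values, so genes near 0 in foregut can move it, and it is not a share of the head with pharynx level. On a linear scale, 195 genes specific to head with pharynx had a median of 1.55 to 1.62% of the way from control foregut in cyclopamine libraries. The median was 0.47 and 0.411% in Rfx6 morpholino replicates 1 and 2, 22.5% in its replicate 3, and 29.7, 30.3 and 73.5% in BMS493 replicates 1, 2 and 3.

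**Figure D1:**
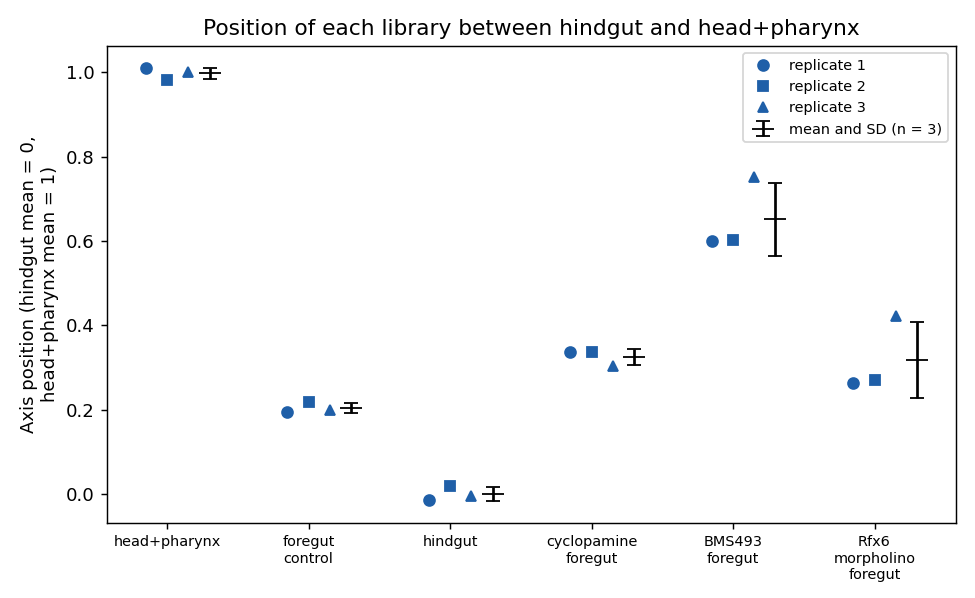
Axis position of each library, a unitless scale with the hindgut mean at 0 and the head with pharynx mean at 1. Points are libraries, with symbols for replicate numbers, and the bars beside them give the mean and SD of 3 libraries. Control foregut sits at 0.204 and BMS493 foregut at 0.652, with replicate 3 above the other libraries in the BMS493 and Rfx6 morpholino groups.

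Cyclopamine was used to ask which foregut genes depend on Hedgehog signalling. In cyclopamine foregut, 1897 of 18542 genes were higher and 1801 lower than in control foregut, of which 339 and 292 changed at least 2-fold, and the median absolute log2 fold change of called genes was 0.49 with a median SE of 0.10. Of posterior genes 706 of 2716 were lower and 94 higher (adjusted p = 0.162 with an estimated correlation). Of anterior genes 448 of 2337 were higher and 80 lower (adjusted p = 0.391 with an estimated correlation). Of 443 foregut-enriched genes 132 were lower and 6 higher, with a median log2 fold change of -0.62 (adjusted p = 0.391 with an estimated correlation). Of 1487 genes enriched in head with pharynx 322 were higher and 12 lower (adjusted p = 0.391 with an estimated correlation). Among 509 hindgut-enriched genes 35 were higher and 68 lower (adjusted p = 0.57 with an estimated correlation). This balance was not seen without control replicate 2 (49 higher and 55 lower of 512) or with treated replicates 1 and 2 summed (18 and 17 of 506). In the list at 4-fold, 7.95% of 88 such genes were higher and 5.68% lower. Their median was 0.0846, against -0.151 in the list at 2-fold. Genes shared by foregut and hindgut included 438 lower and 35 higher of 1410, those shared by head with pharynx and foregut 39 lower and 32 higher of 276, and those lowest in foregut 18 higher of 55. With camera at an estimated correlation their adjusted p was 0.168, 0.391 and 0.162.

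With camera at a preset correlation the posterior list (adjusted p = 1.44e-14), the foregut-enriched list (6.12e-16), the list enriched in head with pharynx (7.14e-13), the anterior list (2.81e-07) and the hindgut-enriched list (0.00957) passed in the cyclopamine comparison. None of these 5 held with an estimated correlation, where the adjusted p was 0.162 for posterior, 0.391 for foregut-enriched, head with pharynx and anterior, and 0.57 for hindgut-enriched genes. For the classes added later, the adjusted p with an estimated correlation was 0.168 for genes shared by foregut and hindgut, 0.391 for those shared by head with pharynx and foregut and 0.162 for those lowest in foregut. Adjusted over the list alone, 939 posterior, 546 anterior, 173 foregut-enriched, 346 head with pharynx and 109 hindgut-enriched genes passed. Leaving out cyclopamine replicate 1 left 1053 higher and 900 lower genes and leaving out replicate 2 left 1084 and 918. Summing replicates 1 and 2, which differed less than other replicate pairs, in all 3 treated groups at once left 602 and 469. Leaving 1 replicate number out of all 3 treated groups left as many libraries. It gave 587 and 487 without replicate 1, 567 and 418 without replicate 2, and 2314 and 2233 without replicate 3. Without control replicate 2 the share of foregut-enriched genes that were lower went from 29.8% to 60.3%, without control replicate 3 to 18.8%, and without cyclopamine replicates 1, 2 or 3 to 15.3, 15.1 or 18.5%. The share of posterior genes that were lower went from 26% to 12.9% without cyclopamine replicate 1 and 13.5% without replicate 2, and total counts alone gave 2529 higher and 1452 lower genes.

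BMS493 was used to ask which foregut genes depend on retinoic acid signalling, and it gave the broadest change. In BMS493 foregut 4139 of 18542 genes were higher and 4511 lower than in control foregut, of which 1147 and 1304 changed at least 2-fold, with a median absolute log2 fold change of 0.59 and a median SE of 0.12 among called genes. Genes enriched in head with pharynx rose, 1312 of 1487 being higher, with a median log2 fold change of 1.3. Genes shared by foregut and hindgut fell, with 1202 of 1410 lower (median -1.08). Of foregut-enriched genes 328 of 443 were lower (median -1.14, adjusted p = 0.134 with an estimated correlation). The share of all counts held by genes shared by foregut and hindgut was 5.86 ± 0.797% in BMS493 foregut against 13 ± 0.452% in control foregut (SD, n = 3), and the share held by genes enriched in head with pharynx was 3.01 ± 0.591% against 1.1 ± 0.0389%.

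Of the anterior list 1715 of 2337 genes were higher and 36 lower in BMS493 foregut, and of the posterior list 1990 of 2716 were lower and 36 higher. Hindgut-enriched genes included 282 lower and 26 higher of 509 (adjusted p = 0.178 with an estimated correlation). Genes shared by head with pharynx and foregut included 89 higher and 20 lower of 276 (adjusted p = 0.0576 with an estimated correlation), and 48 of 55 genes lowest in foregut were higher. With camera at an estimated correlation the posterior list (adjusted p = 0.00101), the anterior list (0.0418), the list enriched in head with pharynx (0.0474), the genes shared by foregut and hindgut (0.00363) and those lowest in foregut (0.0138) passed. The anterior list holds all genes enriched in head with pharynx, and the posterior list all genes shared by foregut and hindgut, so these passes overlap. The foregut-enriched list (adjusted p = 3.76e-25), the hindgut-enriched list (7.23e-11) and the genes shared by head with pharynx and foregut (8.59e-05) passed camera only with the preset correlation. With fry their adjusted p was 0.00039, 0.000721 and 6.44e-05. Adjusted over the list alone, 2127 posterior, 1848 anterior, 346 foregut-enriched, 1379 head with pharynx and 313 hindgut-enriched genes passed. Total counts alone gave 6365 higher and 3237 lower genes, with the median of all genes at 0.13, so the directions given are relative to that shift. Without replicate 3 of the BMS493 and Rfx6 morpholino groups, an alternative added after the data were seen, 1320 of 1511 genes enriched in head with pharynx were higher in BMS493 foregut, with a median of 1.18.

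**Figure D2:**
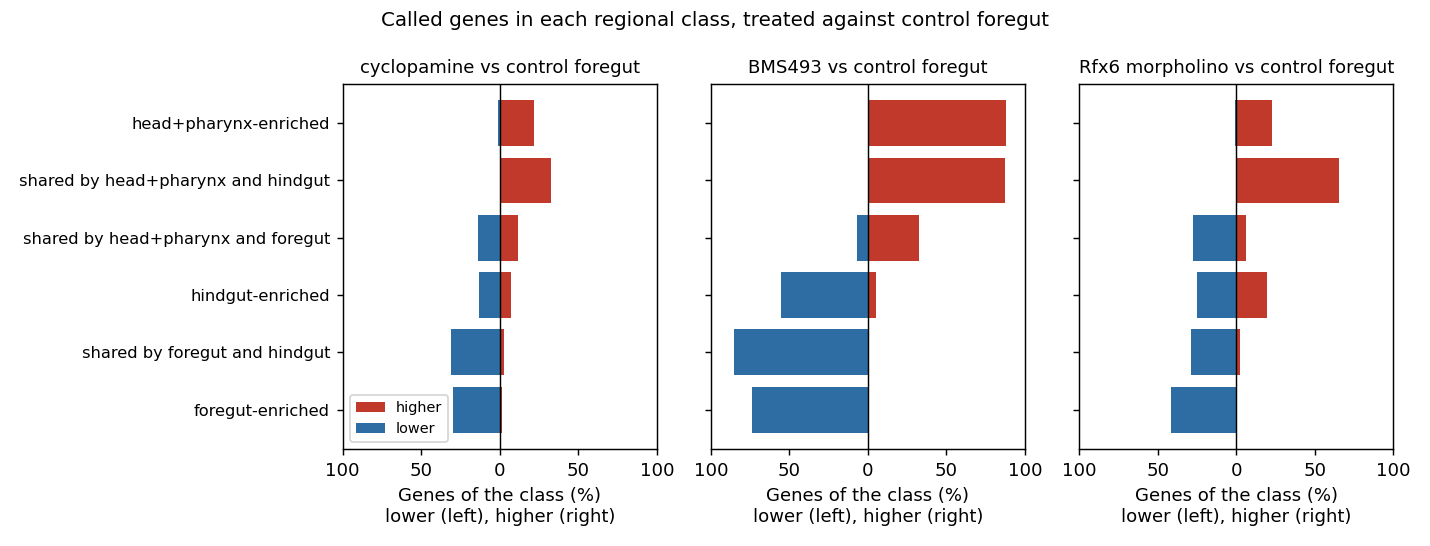
Percent of the genes of each regional class that were called higher (red, to the right) or lower (blue, to the left) than in control foregut, for each treatment. Bars are percentages of genes on an axis from 0 to 100 in each direction, from 3 libraries per group. In BMS493 foregut 88.2% of genes enriched in head with pharynx were higher and 85.2% of genes shared by foregut and hindgut were lower.

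The Rfx6 morpholino was used to ask which foregut genes depend on Rfx6. In Rfx6 morpholino foregut 1530 of 18542 genes were higher and 1667 lower than in control foregut, of which 447 and 367 changed at least 2-fold, with a median absolute log2 fold change of 0.61 and a median SE of 0.13 among called genes. Of foregut-enriched genes 183 of 443 were lower and 2 higher, with a median log2 fold change of -0.72 (adjusted p = 0.157 with an estimated correlation). Genes lowest in foregut rose, 36 of 55 being higher, with a median of 1.11, but they were chosen as low in the same control foregut libraries. Of genes shared by head with pharynx and foregut 76 of 276 were lower and 18 higher (adjusted p = 0.074 with an estimated correlation). Of genes shared by foregut and hindgut 404 of 1410 were lower and 34 higher, and of posterior genes 663 of 2716 were lower and 171 higher (adjusted p = 0.157 with an estimated correlation in both). The level of the Rfx6 transcript is not given, because no identifier could be tied to a symbol.

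The move of Rfx6 morpholino foregut toward head with pharynx was largest in replicate 3, with a mean of 1.67 log2 CPM over genes enriched in head with pharynx, and smaller in replicates 1 and 2, at 0.59 and 0.60 against 0.20 to 0.23 in control foregut. With all libraries 339 of 1487 genes enriched in head with pharynx were higher and 10 lower (median 0.38, adjusted p = 0.333 with an estimated correlation), and 396 of 2337 anterior genes were higher and 175 lower (median 0.12, adjusted p = 0.551 with an estimated correlation). Without replicate 3 of the Rfx6 morpholino and BMS493 groups, an alternative added after the data were seen, 355 of 1511 genes enriched in head with pharynx were higher and 241 lower (median 0.08). Of anterior genes 416 of 2367 were then higher and 498 lower (median -0.03). Both groups keep only replicates 1 and 2 there, which lay closer than other replicate pairs, so these calls may be too many. In that setting 170 of 444 foregut-enriched genes were lower and 9 higher (median -0.55), and 38 of 57 genes lowest in foregut were higher and 2 lower (median 1.06). Hindgut-enriched genes went both ways, with 99 higher and 126 lower of 509 in all libraries, and their median (-0.10) and mean (0.15) differed in sign. The balance turned to 83 higher and 66 lower of 512 without control replicate 2. It turned to 45 higher and 9 lower of 506 with replicates 1 and 2 summed in all 3 treated groups. It was 95 higher and 171 lower of 511 without replicate 3 of both groups. Of the 88 hindgut-enriched genes in the list at 4-fold, 43.2% were higher and 0% lower with all libraries (median 0.996).

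Among the lists of the Rfx6 morpholino comparison, only the genes lowest in foregut passed camera with an estimated correlation (adjusted p = 0.00848). They were chosen as low in the control foregut libraries of this comparison, so part of their rise may be built in. This class was not among those chosen anew with 1 control library, so that check does not cover it. The adjusted p with an estimated correlation was 0.157 for foregut-enriched, posterior and foregut and hindgut shared genes, 0.333 for head with pharynx, 0.551 for anterior, 0.074 for head with pharynx and foregut shared genes and 0.876 for hindgut-enriched genes. With the preset correlation it was 2.66e-30 for foregut-enriched, 1.86e-08 for posterior, 1.85e-14 for head with pharynx, 0.000222 for anterior and 0.472 for hindgut-enriched genes. Adjusted over the list alone, 1010 posterior, 635 anterior, 219 foregut-enriched, 374 head with pharynx and 287 hindgut-enriched genes passed. Leaving out Rfx6 morpholino replicate 1 left 985 higher and 982 lower genes, and leaving out replicate 2 left 931 and 919. A fit of only the 6 libraries compared gave 877 and 856. Summing replicates 1 and 2 in all 3 treated groups at once gave 579 and 541. With 1 replicate number left out of all 3 treated groups there were 607 and 575 without replicate 1, 548 and 516 without replicate 2, and 1943 and 2213 without replicate 3. The share of posterior genes that were lower went from 24.4% to 16.1% without replicate 1 and 15.2% without replicate 2, and total counts alone gave 1893 higher and 1360 lower genes. All classes other than the anterior and posterior lists were chosen on the same control foregut libraries that every treatment is compared with, so their directions are not independent evidence. When foregut-enriched genes were chosen with 1 control library and tested against the others, between 57.5 and 76.8% were lower in BMS493, 15.2 and 42.4% in cyclopamine, and 27.1 and 71% in Rfx6 morpholino foregut. Of genes enriched in head with pharynx chosen in this way, between 76.7 and 79.9% were higher in BMS493, 17.1 and 20.9% in cyclopamine, and 18.6 and 20.4% in Rfx6 morpholino foregut. Hindgut-enriched genes were lower in 53.1 to 60.4% of cases in BMS493 and 15.5 to 20.6% in cyclopamine foregut, but in Rfx6 morpholino foregut their median went from -0.37 (35.2% lower) with control replicate 1 to 0.15 (7.58% lower) with replicate 2.

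Treated groups were compared with each other to test the difference between responses directly. Cyclopamine foregut had 3864 genes higher and 3312 lower than BMS493 foregut, and 1120 of 1487 genes enriched in head with pharynx were lower in cyclopamine foregut while 901 of 1410 genes shared by foregut and hindgut were higher. Rfx6 morpholino foregut had 3653 genes higher and 3212 lower than BMS493 foregut, with 961 of the 1487 lower and 900 of the 1410 higher. Rfx6 morpholino foregut had 1883 genes higher and 2053 lower than cyclopamine foregut, with 134 hindgut-enriched genes higher and 86 lower of 509, and 62 genes shared by head with pharynx and foregut lower and 23 higher of 276. Posterior genes were higher in cyclopamine than in BMS493 foregut (1489 of 2716, adjusted p = 0.0088 with camera at an estimated correlation) and higher in Rfx6 morpholino than in BMS493 foregut (1547 of 2716, 0.00289). With an estimated correlation the adjusted p was 0.0621 and 0.0818 for genes enriched in head with pharynx and 0.0151 and 0.0135 for genes shared by foregut and hindgut in these comparisons. It was 0.906 for hindgut-enriched genes and 0.358 for genes shared by head with pharynx and foregut between Rfx6 morpholino and cyclopamine foregut. Summing replicates 1 and 2 of the treated groups left 1845 higher and 1527 lower genes for cyclopamine against BMS493, 1626 and 1271 for Rfx6 morpholino against BMS493 and 325 and 386 for Rfx6 morpholino against cyclopamine, and total counts alone gave 2744 and 4557 for the first and 2724 and 4800 for the second of these. The Rfx6 morpholino and cyclopamine comparison also fell to 1053 higher and 1212 lower without cyclopamine replicate 1, 1090 and 1253 without cyclopamine replicate 2, 1172 and 1198 without Rfx6 morpholino replicate 1, and 1118 and 1155 without Rfx6 morpholino replicate 2.

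Changes shared by the treatments were counted against the same control libraries. Cyclopamine and BMS493 shared 1111 higher and 1268 lower genes, where independent lists would share 423 and 438. Cyclopamine and the Rfx6 morpholino shared 621 higher and 557 lower genes (157 and 162 for independent lists), and BMS493 and the Rfx6 morpholino 994 and 1174 (342 and 406). All 3 treatments shared 510 higher and 483 lower genes, against 35 and 39 for independent lists, and 217 of the 510 were enriched in head with pharynx while 172 of the 483 were shared by foregut and hindgut and 69 were foregut-enriched. Across genes, which are not independent replicates, fold changes correlated at 0.622, 0.594 and 0.819 for the 3 pairs in the same order, where unchanged groups simulated against the same controls gave 0.539, 0.53 and 0.525. The covariances were 0.461, 0.327 and 0.857 against simulated 0.037, 0.0366 and 0.0362. Replicate 3 stood apart toward head with pharynx in both BMS493 and Rfx6 morpholino foregut, so the 0.819 and 0.857 may rest in part on these libraries. Neither value was computed without them. With both left out, all 3 treatments shared 582 higher genes, 259 of them enriched in head with pharynx, and 596 lower genes. That setting keeps only the close replicates 1 and 2 in both groups, so its calls may be too many. Fold changes had the same sign in 69.9, 66.4 and 68.3% of genes against simulated 67.5, 67.4 and 67.2%, so this share lay below the simulated one for cyclopamine and the Rfx6 morpholino. In the simulations of unchanged groups the pairs shared 0.05 to 0.1 calls on average. Unchanged groups give few calls at this threshold, so that number does not measure how shared controls add to the overlap of changed groups. The 3 control libraries do not give 2 parts of at least 2 libraries and were not split between the treatments, so part of the excess over independent lists may come from the shared controls. Leaving out cyclopamine replicate 1 or 2 left 665 and 656 or 696 and 679 genes shared by cyclopamine and BMS493, and 295 or 308 lower genes shared by cyclopamine and the Rfx6 morpholino (402 higher without replicate 1). Leaving out Rfx6 morpholino replicate 1 or 2 left 364 or 325 lower genes shared with cyclopamine and 780 or 714 lower genes shared with BMS493. Summing treated replicates 1 and 2 left 388 higher and 344 lower genes shared by cyclopamine and BMS493. It left 219 and 126 for cyclopamine and the Rfx6 morpholino, and 451 and 402 for BMS493 and the Rfx6 morpholino. With total counts alone cyclopamine and BMS493 shared 1801 higher genes.

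The 4 single identifiers given here were chosen after their values were seen. XBXT10g018020 stood at 1620 ± 157 CPM in head with pharynx, 0.0592 ± 0.0499 in control foregut and 0.0931 ± 0.0781 in hindgut (SD, n = 3). It reached 21.1 ± 0.823 CPM in cyclopamine, 557 ± 59.4 in BMS493 and 272 ± 188 in Rfx6 morpholino foregut, with log2 fold changes of 8.46 ± 0.89, 13.17 ± 0.81 and 12.14 ± 0.81 (SE) and edgeR adjusted p of 0.000347, 3.29e-06 and 2.36e-05. The Rfx6 morpholino mean rested in part on replicate 3, at 489 CPM, without which it was 163. XBXT10g002589 had no count in control foregut or hindgut, 145 ± 14.4 CPM in head with pharynx and 58 ± 49 in BMS493 foregut, at least 2070-fold higher than the floor of 3 counts over the control group (edgeR adjusted p = 0.04, and 0.0651 to 0.0823 when any library of the comparison was left out). BMS493 replicate 3 stood at 115 CPM, and without it the mean was 29.7 CPM, or at least 1060-fold over the floor. XBXT10g007785, at 7.69 ± 0.351 CPM in head with pharynx and 0.244 ± 0.0406 in hindgut, fell from 16.4 ± 2.85 CPM in control to 3.3 ± 0.184 in cyclopamine foregut (log2 fold change -2.32 ± 0.14, edgeR adjusted p = 1.07e-06) and stood at 8.93 ± 0.818 in BMS493 and 4.47 ± 0.579 in Rfx6 morpholino foregut. XBXT10g028408, at 19.8 ± 2.45 CPM in hindgut and 0.15 ± 0.0439 in head with pharynx, fell from 12.7 ± 2.4 in control to 1.2 ± 0.2 in BMS493 foregut (log2 fold change -3.39 ± 0.16, edgeR adjusted p = 5.89e-08).

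**Figure D3:**
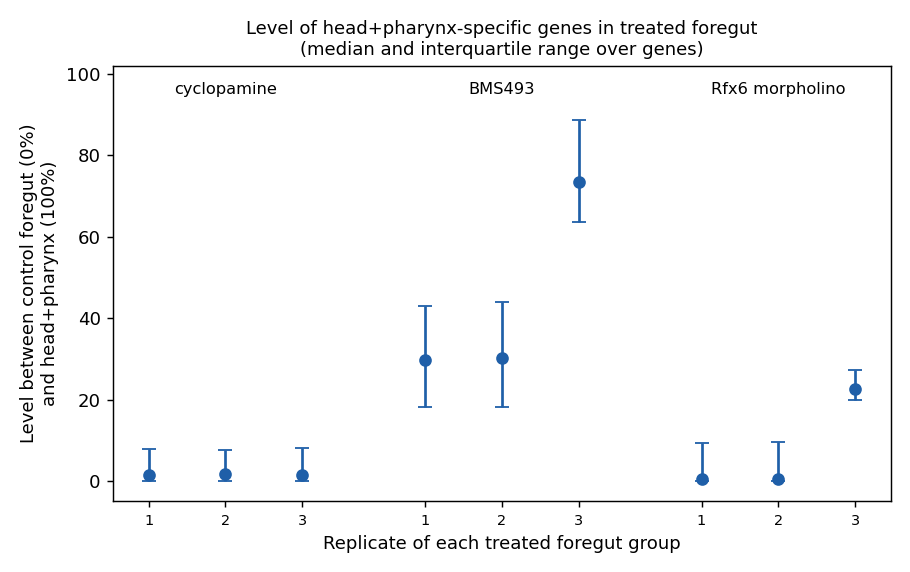
Level of genes specific to head with pharynx in each treated foregut library, in percent of the way from control foregut (0) to head with pharynx (100). Points are medians and bars interquartile ranges over 195 genes. BMS493 replicate 3 sits at 73.5% and replicates 1 and 2 at 29.7 and 30.3%, Rfx6 morpholino replicate 3 at 22.5% and its replicates 1 and 2 at 0.47 and 0.411%, and the cyclopamine libraries between 1.55 and 1.62%.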

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

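Of the settings below, the summed replicates, the removal of 1 replicate number from all 3 treated groups, the joint removal of replicate 3 from BMS493 and Rfx6 morpholino, and the lists chosen with 1 control foregut library were chosen after the results were seen, as was the use of percent of a list. Counts of genes per comparison, enriched sets and overlaps stayed within 1.5 times under RLE scaling, no filter, the stricter filter, DESeq2 and the fit of all 18 libraries (27 of 27 each), and under the joint removal of replicate 3 from BMS493 and Rfx6 morpholino (16 of 16) or from all 3 treated groups (18 of 18). The replicate block moved no count by over 1.5 times (27 of 27). It changed no list call against control foregut or between Rfx6 morpholino and BMS493. Where the numbers passed the rule for pairs, it gave 3397 higher and 3317 lower genes for foregut against hindgut. For Rfx6 morpholino against BMS493 it gave 3809 and 3667. Under the block, cyclopamine gave 2151 and 1988, BMS493 4399 and 4651 and the Rfx6 morpholino 1708 and 1852 genes against control, where the libraries share only a number. The block moved 3 list calls across the threshold, in comparisons that did not pass the rule for pairs. Genes enriched in head with pharynx passed between cyclopamine and BMS493 (adjusted p = 0.0327 with an estimated correlation, 0.0621 without the block), and genes lowest in foregut (0.0155 and 0.233) and hindgut-enriched genes (0.0349 and 0.0802 with the preset correlation) between Rfx6 morpholino and cyclopamine. The causes of the changes below were not tested, unless the setting itself names them, such as fewer libraries or a stricter limit.

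At least 2-fold left 2421 higher and 1801 lower genes for foregut against head with pharynx, 1094 and 702 for foregut against hindgut, 2752 and 2456 for hindgut against head with pharynx, 339 and 292 for cyclopamine, 1147 and 1304 for BMS493, 447 and 367 for the Rfx6 morpholino, 765 and 842 for cyclopamine against BMS493, 919 and 807 for Rfx6 morpholino against BMS493 and 414 and 343 for Rfx6 morpholino against cyclopamine. With total counts alone foregut against head with pharynx had 7495 lower genes, foregut against hindgut 5320 higher, hindgut against head with pharynx 3966 higher and 8919 lower, and BMS493 6365 higher, while 1801 genes were higher in both drugs. The axis position then was 0.186 for control and 0.304 for cyclopamine foregut, and with lists at 4-fold 0.178 and 0.299. Medians of genes enriched in head with pharynx rose with lists at 4-fold. They were 0.829 in cyclopamine, 2.94 in BMS493 and 1.82 in Rfx6 morpholino foregut, against 0.323, 1.3 and 0.378 at 2-fold. The Rfx6 morpholino medians include replicate 3. Without replicate 3 of BMS493 and Rfx6 morpholino its median at 2-fold was 0.0801, and medians at 4-fold were not computed in that setting. For foregut-enriched genes they were -0.725, -1.17 and -0.938, against -0.625, -1.14 and -0.718.

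Limma on log2(TPM + 1) gave 3337 higher genes for foregut against head with pharynx, 1792 lower for foregut against hindgut, 3563 higher for hindgut against head with pharynx, 1093 lower for cyclopamine, 2821 lower for BMS493, 2083 higher for cyclopamine against BMS493, 1971 higher and 5147 lower for Rfx6 morpholino against BMS493 and 1159 higher for Rfx6 morpholino against cyclopamine. It gave 288 foregut-enriched and 256 hindgut-enriched genes, 738 genes lower in both drugs and 403 higher in cyclopamine and the Rfx6 morpholino. Fits of only the 6 libraries compared gave 877 higher and 856 lower genes for the Rfx6 morpholino, 352 higher with cyclopamine as well, 569 higher and 648 lower with BMS493 as well, and 15.9% of posterior genes lower.

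With treated replicates 1 and 2 summed, which leaves 2 libraries in each treated group, there were 602 higher and 469 lower genes for cyclopamine, 579 and 541 for the Rfx6 morpholino, 1845 and 1527 for cyclopamine against BMS493, 1626 and 1271 for Rfx6 morpholino against BMS493, and 325 and 386 for Rfx6 morpholino against cyclopamine. Shared higher and lower genes were 388 and 344 for the drugs, 219 and 126 for cyclopamine and the Rfx6 morpholino, and 451 and 402 for BMS493 and the Rfx6 morpholino. In cyclopamine foregut 9.49% of anterior and 12.2% of head with pharynx genes were higher and 7.85% of posterior and 8.58% of foregut-enriched genes lower. In Rfx6 morpholino foregut 11% of anterior genes were higher and 9.4% of posterior and 22.8% of foregut-enriched genes lower. Lists chosen with control replicate 1 alone had 15.2% of foregut-enriched genes lower in cyclopamine and 27.1% in Rfx6 morpholino foregut, those with replicate 2 had 71% lower in Rfx6 morpholino foregut, and those with replicate 3 had 15.4% lower in cyclopamine foregut.

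Leaving out 1 replicate number from all 3 treated groups leaves as many libraries as the sums. Without replicate 1 there were 587 higher and 487 lower genes for cyclopamine, 607 and 575 for the Rfx6 morpholino, 1729 and 1684 for cyclopamine against BMS493, 1517 and 1312 for Rfx6 morpholino against BMS493, and 335 and 360 for Rfx6 morpholino against cyclopamine. Shared higher and lower genes were then 394 and 351 for the drugs, 220 and 131 for cyclopamine and the Rfx6 morpholino, and 471 and 435 for BMS493 and the Rfx6 morpholino. Without replicate 2 the numbers were 567 and 418, 548 and 516, 1768 and 1463, 1549 and 1215, and 314 and 375, and for shared genes 369 and 299, 202 and 115, and 432 and 375, in the same order. Without replicate 3, which keeps the close replicates 1 and 2, cyclopamine gave 2314 and 2233 genes and the Rfx6 morpholino 1943 and 2213.

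With an estimated correlation the adjusted p in camera was 0.391 for foregut-enriched, head with pharynx and anterior genes in cyclopamine foregut, 0.57 for hindgut-enriched and 0.162 for posterior genes. In BMS493 foregut it was 0.134 for foregut-enriched and 0.178 for hindgut-enriched genes, and in Rfx6 morpholino foregut 0.157 for foregut-enriched and posterior, 0.333 for head with pharynx and 0.551 for anterior genes. With fry it was 0.0544 for foregut-enriched, 0.0558 for head with pharynx, 0.286 for hindgut-enriched and 0.0745 for anterior genes in cyclopamine foregut. In Rfx6 morpholino foregut it was 0.194 for anterior genes. Other lists named here passed fry, namely posterior genes in cyclopamine (0.00428) and foregut-enriched (0.00039) and hindgut-enriched genes (0.000721) in BMS493 foregut. In Rfx6 morpholino foregut foregut-enriched and posterior genes (0.0081 in both) and head with pharynx genes (0.0472) passed fry.

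Leaving out each library in turn kept 162 counts of genes within 1.5 times and moved 27. The range was 1053 to 2207 higher and 900 to 2243 lower genes for cyclopamine, 931 to 1578 and 919 to 1821 for the Rfx6 morpholino, and 1053 to 1926 and 1155 to 2275 for Rfx6 morpholino against cyclopamine. Shared higher and lower genes ranged from 665 to 1367 and 656 to 1680 for the drugs, 402 to 671 and 295 to 656 for cyclopamine and the Rfx6 morpholino, and shared lower genes from 714 to 1156 for BMS493 and the Rfx6 morpholino. The share of lower genes ranged from 12.9 to 32% of the posterior and 15.1 to 60.3% of the foregut-enriched list in cyclopamine foregut and from 15.2 to 25.7% of the posterior list in Rfx6 morpholino foregut. The call of XBXT10g002589 in BMS493 foregut (edgeR adjusted p = 0.04) was also lost without a filter (0.0518) and with summed replicates (0.116), which also ended the call of XBXT10g028408 in Rfx6 morpholino foregut (0.0769). The shallowest library held 26006163 counts. Genes changed 1.5-fold and expected at 50 counts or more were recovered in 50 to 64% of simulated cases, so smaller changes can be missed. How much of this comes from depth and how much from the number of libraries was not separated.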

Other observations

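Apart from the splits of the libraries and the tests of even carry-over and dilution in the BMS493 group as a whole and in Rfx6 morpholino replicate 3, all tests in this part were chosen after the results were seen. Some genes set a treatment apart, being changed in 1 direction against control foregut and against both other treatments (edgeR's quasi-likelihood test, adjusted p under 0.05 in each). In Rfx6 morpholino foregut 271 genes were higher in this way. Of these 66 (24.4%) were hindgut-enriched, against 2.78% of the 18288 genes tested (odds ratio 13.2, Fisher's exact test, adjusted p = 2.93e-43 over genes, which are not independent). The classes were chosen on the same control foregut libraries, so part of such an excess may be built in. As a list, hindgut-enriched genes did not pass camera with an estimated correlation against control (adjusted p = 0.876), cyclopamine (0.906) or BMS493 foregut (0.173). Their median against control went from -0.37 to 0.15 with the control library used to choose them. Another 261 genes were lower in this way, and 31 of them were foregut-enriched. Of the 261, 38 (14.6%) were shared by head with pharynx and foregut, against 1.51% of tested genes (odds ratio 12.9, Fisher's exact test, adjusted p = 8.7e-26). With camera at an estimated correlation that class passed against BMS493 foregut (adjusted p = 0.00289), but not against control (0.074) or cyclopamine foregut (0.358). Without replicate 3 of the Rfx6 morpholino and BMS493 groups, 62 of 414 higher genes were hindgut-enriched and 57 of 698 lower genes were shared by head with pharynx and foregut. Of these lower genes 198 were enriched in head with pharynx, against 7 of 261 with all libraries. Both groups keep only the close replicates 1 and 2 in that setting, so its calls may be too many. In BMS493 foregut 791 of 1637 such higher genes were enriched in head with pharynx and 674 of 1950 lower genes were shared by foregut and hindgut. Cyclopamine set apart 414 higher and 232 lower genes, of which 9 and 6 were enriched in head with pharynx.

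Genes changed the same way by both drugs were also compared with Rfx6 morpholino foregut, where the labels name a morpholino as they do for control foregut. Of 1111 genes higher in both drugs 299 were also higher than in Rfx6 morpholino foregut in both, and of 1268 lower genes 422 were lower. The labels do not state whether the drug-treated embryos were injected, so these genes cannot be assigned to the drugs or to an injection.

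The BMS493 libraries lay at 0.6 to 0.752 on the axis where control foregut lay at 0.204 ± 0.012, and scaling as the cause is argued against by the posterior list, which kept a median log2 change of -0.759 with total counts alone, and a morpholino missing from the drug groups, if it was, as the whole cause by cyclopamine foregut, whose labels name none either and which was lower than BMS493 foregut in 1120 of 1487 genes enriched in head with pharynx (median -1.03), if cyclopamine does not counter it. Even carry-over of head and pharynx tissue is argued against for replicates 1 and 2, with a relative interquartile range of the implied share of 0.832 and 0.851 against at most 0.28 in 9 mock mixtures, and with 388 foregut genes that head with pharynx lacks at a median log2 change of -1.39 where the implied shares of 29.7 and 30.3% would give -0.51 and -0.52. For replicate 3 it was not excluded, as against control its range was 0.342 and its foregut genes stood at -1.98 where a share of 73.5% gives -1.92, and against replicates 1 and 2 the criterion first set was met (0.179 against 0.274 in mock mixtures). Against it as what sets replicate 3 apart from replicates 1 and 2 speaks a share of 116% (interquartile range 107 to 128), by a criterion set after that value was seen, while 134 foregut genes stood at a median log2 ratio of -0.74, and a share of 100% would leave none of them, but the share rests on 17 genes, fewer than the 20 then required, so this stays open. Dilution by tissue without foregut genes (interquartile range of log2 ratios 0.76, against 1.13 in mock mixtures, a wide limit), carry-over of part of the head tissue and a shift of foregut expression toward anterior fates under retinoic acid receptor inhibition, which may act together, stay open.

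Rfx6 morpholino replicate 3 lay at 0.422 on the axis, apart from replicates 1 and 2 at 0.263 and 0.27. Even carry-over of head and pharynx tissue is a candidate explanation for the genes of head with pharynx, since 152 genes specific to that tissue implied a share of 21.3% (interquartile range 19.3 to 22.7) with a relative range of 0.162, against up to 0.283 in mock mixtures, and dilution of foregut genes was also compatible (0.298 against 1.12). Hindgut-enriched genes had a mean of 2.93 log2 CPM there, against 2.55 and 2.52 in replicates 1 and 2 and 0.95 to 1.12 in head with pharynx. Carry-over can raise or lower a mean of log2 values, since genes nearly absent from foregut can rise steeply. Whether it accounts for this difference is therefore not decided. Cyclopamine replicate 3 differed in the same direction (2.69 against 2.35 and 2.33). An exchange with a BMS493 library was not excluded by the criterion first set, as the centred profile correlated at -0.038 with its own group and 0.399 with BMS493, a difference of -0.437, and the criterion was then changed to ask for a BMS493 library out of place, where each lay nearer its own group, by at least 1.19. A wrong label without an exchange needs no such partner and stays open, although the 2.93 lay outside the 1.88 to 2.04 of the BMS493 libraries, and a stronger response to the morpholino in this pool was not tested.

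Replicates 1 and 2 of each treated group lay closer to each other than all 15 other replicate pairs, with a biological coefficient of variation of at most 0.0564 against at least 0.0673. The same library deposited again is argued against by a median chi-square ratio of at least 2.48, where sampling noise gives about 1. They were the closest pair in all 3 treated groups (0.0396 for cyclopamine, 0.0249 for BMS493 and 0.0564 for Rfx6 morpholino). In each control group replicates 1 and 3 were the closest (0.0711 in head with pharynx, 0.0894 in foregut and 0.0673 in hindgut). The same numbers in all 3 treated groups argue against chance closeness of single pairs. Whether explants, embryos or RNA were shared between treated replicates 1 and 2 is not decided, as no label gives the clutch or pool. If they were shared, p-values of the treated groups could be too small. At equal numbers of libraries the calls differed with the replicate left out. For cyclopamine there were 602 higher and 469 lower genes with each pair summed, 587 and 487 without replicate 1 of all 3 treated groups and 567 and 418 without replicate 2. Without replicate 3, which keeps the pair, there were 2314 and 2233. With replicate 3 removed only from BMS493 and Rfx6 morpholino, cyclopamine kept its 3 libraries and gave 2444 and 2369. The effect of the pair was thus not separated from that of losing those replicates from the shared fit.

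The real grouping of the 6 libraries was set beside the other splits, 10 in all for each comparison, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes in edgeR. It gave 9549 genes for foregut against head with pharynx, 5119 for foregut against hindgut, 12392 for hindgut against head with pharynx, 2926 for cyclopamine, 7047 for BMS493, 8363 for cyclopamine against BMS493, 6970 for Rfx6 morpholino against BMS493 and 5178 for Rfx6 morpholino against cyclopamine, where the highest of the other splits gave 0 genes in each. For the Rfx6 morpholino it gave 1733 and the highest other split 1. Each of the other splits puts libraries of both groups on each side. A real difference then widens the spread within a side and leaves few calls, so these numbers do not measure false calls. At an unadjusted p under 0.05 the other splits gave between 20 genes, in a split of hindgut and head with pharynx, and 1329, in a split of cyclopamine and control foregut. For foregut against hindgut and Rfx6 morpholino against BMS493, where the numbers passed the rule for pairs, 4 splits part 3 pairs. The others of these gave 0 genes as well.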
